A study of Astyanax mexicanus with 36 samples.

How the data were processed

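Oocytes of 4 size categories were taken from right ovaries of surface, Pachón and Molino Astyanax mexicanus, 3 libraries per group and 36 in all. Per the labels' protocols, RNA was extracted with Trizol and RNeasy columns, ribosomal RNA was depleted, and directional libraries were made with input masses and PCR cycles that varied between samples, then sequenced on a Singular Genomics G4. The labels do not say whether 40um and 300um are bounds or midpoints, nor which library had which input. Per the submitters' processing notes, STAR 2.7.10b and RSEM were used; the genome build is not given in the sources used here. The deposited count table holds integer read counts for 27420 Ensembl genes, 16752 of them with a symbol and 1887 sharing a symbol with another gene, and 4 entries of unassigned reads. The deposited CPM table holds normalised signal values for 18259 genes, which equal edgeR's CPM with TMM scaling of the genes that pass edgeR's expression filter over all 36 libraries. Tests used the counts; the normalised table was used only in that check.

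Unassigned reads were left out of library sizes and tests: reads in no annotated gene made up 20.5% of each library on average, multimapping reads 12.6% and unmapped reads 9.59%, and 56.9% were assigned to genes. Library numbers in the labels form 3 series: 1 for 300um, 1 for the 2 middle categories and 1 for 40um, so size contrasts that involve 40um or 300um are also contrasts of series.

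Populations were compared in pairs within each size category, fitting the 9 libraries of that size. Neighbouring size categories averaged over populations, 300um against 40um within each population, and the difference of that change between each cave population and surface fish were tested in a fit of all 36 libraries, giving 20 contrasts. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), leaving 15917, 14377, 15494 and 15214 genes at the 4 sizes in rising order and 18259 in the fit of all libraries. Counts were scaled with TMM and tested with edgeR 4.0.16's quasi-likelihood F test (robust dispersions) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; every adjusted p of a gene comes from that test. The common dispersion was 0.246 at 40um, from 0.0509 to 0.0691 at the other sizes and 0.129 in the fit of all libraries. For a group without reads, the fold is given as at least the value reached when 3 counts are set over that group, the 95% upper limit for a count of 0; for groups with 1 to 3 reads the ratio is given with its 95% counting interval.

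Before the data were examined, 31 gene lists were written: oocyte factors, germline stem and early germ cells, meiosis, piRNA pathway, granulosa cells, steroidogenesis, stroma and smooth muscle, endothelium, erythrocytes, macrophages and granulocytes, lymphocytes, hepatocyte and plasma proteins, yolk uptake and processing, cholesterol synthesis, lipid synthesis and storage, fatty acid oxidation and lipolysis, glycolysis and gluconeogenesis, nuclear oxidative phosphorylation, mitochondrially encoded genes (which matched no gene in the table), cytosolic ribosomal proteins, proteasome, cell cycle, DNA damage and repair, apoptosis, heat shock and unfolded protein response, antioxidant defence, insulin, IGF and mTOR signalling, circadian clock and light response, genes with known cavefish alleles or loss, innate inflammation, and WNT, BMP and TGF beta signalling. Lists with at least 5 tested members were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted within the population, size and interaction families, and beside it with an estimated correlation and with fry.

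Genes named in the text follow a rule set before the data were examined: per contrast the 3 (populations), 5 (sizes and interactions) or 10 (all 4 sizes) largest changes each way among genes past the threshold with a symbol, a mean log2 CPM of at least 2 and libraries that do not overlap between the groups; up to 4 called members of each list; and the anchors gdf9, bmp15, figla, zp3, ddx4, sycp3, amh, cyp19a1a, foxl2a, fshr, star, cyp17a1, cyp11a1, vtg1, plin2, oca2 and per2, of which zp3, cyp11a1 and vtg1 matched no gene. Overlap was not considered for interactions. Some genes that the rule names are not reported here.

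The alternatives tried were DESeq2's size factors, library totals, no expression filter, DESeq2 1.42.0's Wald test, leaving out the 50 most abundant genes, 1 fit of all 36 libraries, only the libraries compared, replicate blocks, and each library left out in turn. Chosen after seeing the data were the summed markers of other cell types as a covariate, leaving out 2 libraries with raised markers, and 3 sizes without 40um. The gene tests were tested on simulated data in which 200 genes changed by known folds. For Pachón against surface at 40um (15611 genes) they recovered 0% of changes of 2-fold, 22% of 4-fold, 56% of 8-fold and 78% of 16-fold, and at 300um (14875 genes) 38%, 76%, 82% and 96%; for the interaction (17306 genes) 8%, 56%, 62% and 72%. Between 1.98% and 5.13% of calls were false. In the list simulation 1 of 29 lists was called, the list raised 1.5-fold.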

Results

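Total RNA was sequenced in bulk from oocytes of the Mexican tetra, Astyanax mexicanus, sorted by size. The species has eyed surface and blind cave forms. The oocytes came from the right ovaries of adults about 520 days old, from surface fish and from the Pachón and Molino cave populations. Fish oocytes grow inside a follicle, so the size categories order the samples along that growth. Each of the 3 populations had 3 libraries in each of 4 size categories, labelled 40um, 40_100um, 100_300um and 300um, or 36 in all. The labels do not say whether replicates came from separate fish, so p-values measure the spread between these samples, which may be technical.

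The count table held 27420 genes, of which 26012 had at least 1 read. Reads assigned to genes ranged from 2.99 to 9.35 M per library, with a mean of 6.59 M. The 40um libraries had 2.99 to 6.87 M, and on average 36.4% of their reads were assigned to genes, against 67.7% at 40_100um, 64.7% at 100_300um and 59% at 300um. Replicates of a group differed by more than counting noise in every pair (chi-square per degree of freedom 2.54 to 158), so no library counted as a duplicate. Changes are log2 fold changes with their standard error (SE), and levels are CPM after TMM scaling, as mean ± SD.

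First, 40_100um was compared with 40um, averaged over the 3 populations. Gdf9 and bmp15, growth factors secreted by oocytes, were higher at 40_100um by 2.19 (SE 0.17, adjusted p = 5.01e-12; 66.97 ± 12.2 against 15.4 ± 7.64 CPM, n = 9) and 2.02 (SE 0.22, adjusted p = 2.83e-09). The germline RNA helicase ddx4 rose by 1.97 (SE 0.20, adjusted p = 4.51e-10). Genes of follicle, blood and immune cells were far lower: the follicle-stimulating hormone receptor fshr by -5.55 (SE 0.37, adjusted p = 3.99e-13; 1.35 ± 1.54 against 49.9 ± 41.9 CPM, n = 9), the aromatase cyp19a1a by -6.29 (SE 0.71, adjusted p = 5.87e-09), the haemoglobin gene hbba2 by -8.09 (SE 0.45, adjusted p = 1.91e-14) and the complement gene c1qc by -9.41 (SE 1.00, adjusted p = 3.47e-09). In all, 13423 of 18259 tested genes differed, 5434 higher and 7989 lower at 40_100um. The median change of all genes was -0.32.

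**Figure D1:**
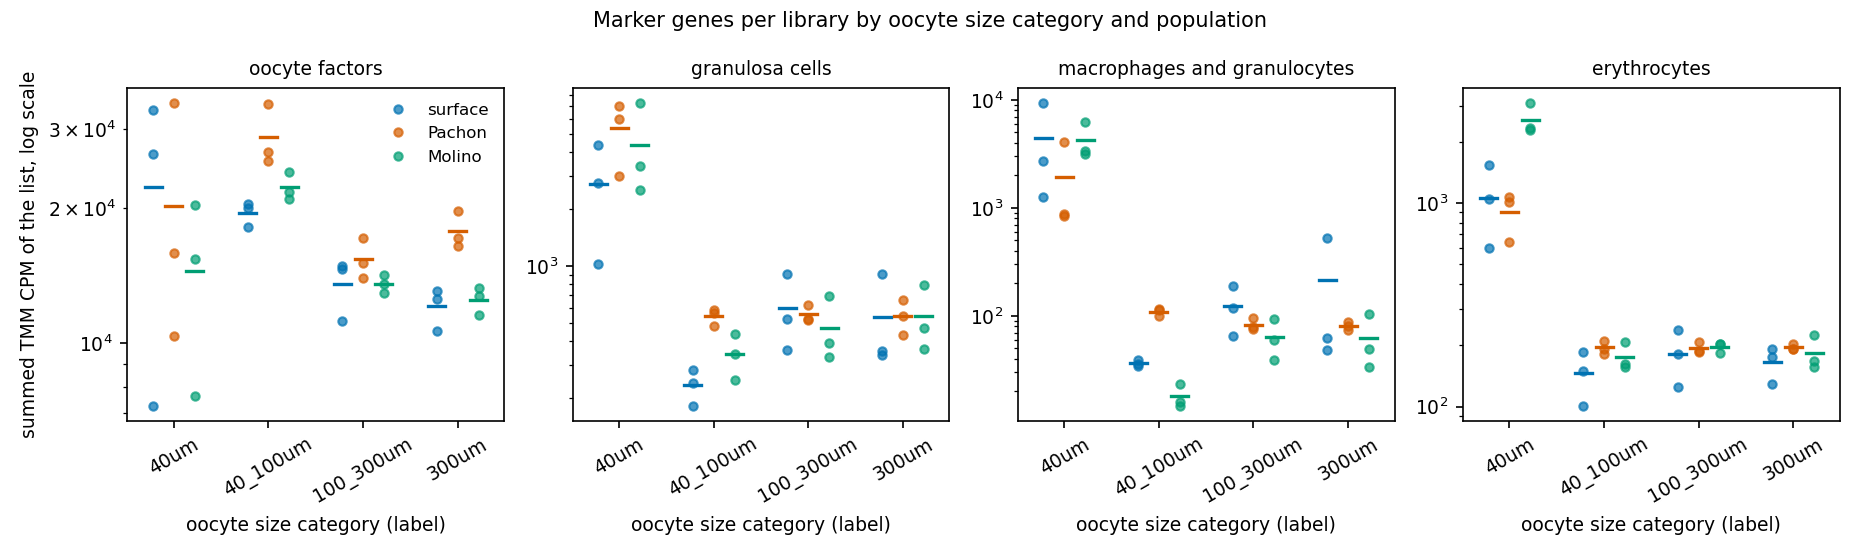
Summed CPM of 4 marker lists on a log scale for each of the 36 libraries, by oocyte size category and population. Points are libraries and bars are the means of 3. Macrophage and granulocyte markers summed to at least 844 CPM in each 40um library and to at most 529 CPM in any library of the other sizes.

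The lists of somatic cell markers fell together at this step. Of 33 granulosa cell genes 30 fell and 1 rose (median -4.79, list test adjusted p = 1.21e-07), of 24 macrophage and granulocyte genes 24 fell (median -7.99, adjusted p = 1.57e-06), and of 27 inflammation genes 24 fell (median -4.62, adjusted p = 2.18e-06). These 3 lists had an adjusted p = 0.633 with an estimated correlation. Of 20 steroidogenesis genes 15 fell and 2 rose (median -3.56, adjusted p = 0.0125, adjusted p = 0.633 with an estimated correlation), among them star, which carries cholesterol into mitochondria (-5.07, SE 0.55, adjusted p = 2.74e-09). Of 16 erythrocyte genes 14 fell (median -4.90, adjusted p = 3.04e-07, adjusted p = 0.304 with an estimated correlation). Among stroma and smooth muscle genes 22 of 26 fell and 1 rose (median -3.75, adjusted p = 0.00206), among endothelial genes 19 of 20 fell (median -3.20, adjusted p = 0.00558), and among lymphocyte genes 17 of 20 fell and 1 rose (median -5.67, adjusted p = 0.0141). These had adjusted p = 0.662, 0.665 and 0.701 with an estimated correlation. Ribosomal protein genes moved the same way as the markers of other cells, with 84 of 91 lower and 4 higher (median -1.25, adjusted p = 6.5e-18, adjusted p = 0.633 with an estimated correlation), as did insulin, IGF and mTOR genes (28 of 43 lower, 8 higher, median -1.17, adjusted p = 0.01, adjusted p = 0.633 with an estimated correlation) and clock and light response genes (28 of 39 lower, 7 higher, median -1.49, adjusted p = 0.00401, adjusted p = 0.659 with an estimated correlation). Adjusted over the list alone, the counts were the same except for 15 erythrocyte genes and 18 lymphocyte genes lower.

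Of 42 cell cycle genes 32 rose and 5 fell at 40_100um (median 1.07, adjusted p = 5.57e-08, adjusted p = 0.633 with an estimated correlation), led by the replication helicase subunit mcm5 (2.604, SE 0.19, adjusted p = 2.19e-12) and the kinetochore motor cenpe (2.599, SE 0.17, adjusted p = 3.12e-13), while the growth-phase cyclin ccnd1 fell by 3.33. Of 45 DNA repair genes 30 rose and 7 fell, or 31 and 7 adjusted over the list alone (median 0.73, adjusted p = 0.00318, adjusted p = 0.657 with an estimated correlation). In the piRNA pathway 10 of 14 genes rose and 2 fell (median 0.79, adjusted p = 0.0188, adjusted p = 0.659 with an estimated correlation), including tdrd1 (1.76, SE 0.18, adjusted p = 6.66e-10). Of 13 germline stem and early germ cell genes 4 rose and 7 fell, and of 20 meiosis genes 5 rose and 8 fell. Neither list passed (adjusted p = 0.876 and 0.657). Of 32 oocyte factors 17 rose and 5 fell (adjusted p = 0.0411, adjusted p = 0.828 with an estimated correlation). Their median was 0.40 but their mean was -0.04, lowered by members such as gpr3 (-5.76), and figla fell by 0.98 (adjusted p = 0.00174). Proteasome genes also split, with 21 of 47 higher and 7 lower (median 0.23, mean -0.48, adjusted p = 0.026, adjusted p = 0.815 with an estimated correlation). As many members passed adjusted over the list alone for the oocyte factors, piRNA, cell cycle and proteasome lists. The 40um libraries carry library numbers of a separate series, so size and series cannot be told apart here.

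The step from 40_100um to 100_300um lies within 1 library series. Some follicle and steroid hormone genes were higher at 100_300um: the estradiol-forming enzyme hsd17b1 by 3.38 (SE 0.56, adjusted p = 4.57e-05; 13.5 ± 11.6 against 1.82 ± 1.84 CPM, n = 9), fshr by 2.76 (SE 0.37, adjusted p = 3.29e-06), the receptor notch3 by 2.63 (SE 0.50, adjusted p = 0.000225), star by 2.88 (SE 0.55, adjusted p = 0.000237) and cyp19a1a by 2.45 (SE 0.66, adjusted p = 0.00524). Some maternal factors were lower: zar1 by -1.06 (SE 0.28, adjusted p = 0.00459; 751 ± 160 against 1608 ± 509 CPM, n = 9), the nuclear chaperone npm2b by -0.93 (SE 0.28, adjusted p = 0.0129) and the egg coat gene zp2l1 by -1.15 (SE 0.30, adjusted p = 0.00462). Of 18259 genes 6022 differed, 4494 higher and 1528 lower. The median change of all genes was 0.19.

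Among granulosa cell genes 22 of 33 rose and none fell (median 1.49, list test adjusted p = 6.45e-05, adjusted p = 0.657 with an estimated correlation). The counts were 22 and 1 adjusted over the list alone. Of 20 steroidogenesis genes 7 rose and 1 fell (7 and 2 adjusted over the list alone). That list did not pass (adjusted p = 0.359). Of 26 stroma and smooth muscle genes 16 rose, or 18 adjusted over the list alone (median 1.53, adjusted p = 0.016, 0.0815 with library totals as the scaling, adjusted p = 0.811 with an estimated correlation). Of 27 inflammation genes 11 rose, or 12 adjusted over the list alone (median 1.202, adjusted p = 0.0459, 0.18 with library totals, adjusted p = 0.815 with an estimated correlation). Insulin, IGF and mTOR genes included 23 of 43 higher and 3 lower, or 25 and 3 adjusted over the list alone (median 0.57, adjusted p = 0.00445, adjusted p = 0.633 with an estimated correlation), such as the transcription factor foxo1b (2.27, SE 0.25, adjusted p = 3.48e-07). Of 39 clock and light response genes 16 rose and 1 fell, or 19 and 1 adjusted over the list alone (median 0.73, adjusted p = 0.0131, adjusted p = 0.659 with an estimated correlation). Cry2, a repressor of the clock, rose by 1.31 and the light-induced per2 by 0.81 (adjusted p = 0.0118).

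Lists of translation, respiration and protein turnover had negative medians at this step. Of 91 genes in the ribosomal protein list 64 fell and 3 rose, or 67 and 3 adjusted over the list alone (median -0.49, adjusted p = 3.91e-26, adjusted p = 0.561 with an estimated correlation). The 3 that rose are S6 kinases, not ribosomal proteins, namely rps6ka4 (1.11), RPS6KA5 (1.02) and RPS6KA2 (0.89). Of 92 nuclear oxidative phosphorylation genes 46 fell and 1 rose, or 54 and 1 adjusted over the list alone (median -0.41, adjusted p = 1.15e-16, adjusted p = 0.633 with an estimated correlation), such as cox6c of complex IV (-0.76, SE 0.11, adjusted p = 6.82e-06). Oocyte factors included 18 of 32 lower and 1 higher, with the same counts adjusted over the list alone (median -0.59, adjusted p = 3.53e-08, adjusted p = 0.633 with an estimated correlation), and gdf9 fell by 0.46 (adjusted p = 0.0263, not past the threshold with library totals). Of 47 proteasome genes 15 fell and 1 rose, or 16 and 1 adjusted over the list alone (median -0.28, adjusted p = 4.45e-06, adjusted p = 0.633 with an estimated correlation). Among 42 cell cycle genes 9 fell and 3 rose, or 8 and 3 adjusted over the list alone (median -0.17, which became 0.04 with library totals, adjusted p = 0.00539, adjusted p = 0.815 with an estimated correlation). Surface 100_300um replicate 1 had raised markers of other cell types (summed log2 CPM 11.99, against 10.86 and 10.79 in its replicates). Without it 3499 genes were higher and 2449 lower. The split of 4494 and 1528 also depended on scaling: it was 6391 and 387 with library totals, 3904 and 2627 with DESeq2's size factors, and 3969 and 2416 without the 50 most abundant genes.

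Between the 300um and the 100_300um category 73 of 18259 genes differed, 36 higher and 37 lower, or 195 with a block for population and replicate number. Higher at 300um were the luteinising hormone receptor lhcgr (3.04, SE 0.41, adjusted p = 0.000501; 30.8 ± 18.95 against 3.41 ± 1.18 CPM, n = 9), cmah (3.71, SE 0.57, adjusted p = 0.00119), the GABA transporter slc6a11a (3.04, SE 0.50, adjusted p = 0.00173), the steroid enzyme hsd17b3 (2.75, SE 0.55, adjusted p = 0.0108), CPA1 (1.97) and the gonadal growth factor igf3 (1.70). Lower were fstl3, which binds activin (-2.53, SE 0.37, adjusted p = 0.000729), sall1a (-2.42), the ligands wnt9b (-2.06) and wnt4 (-3.21), hsd17b1 (-2.22, adjusted p = 0.0332) and inhbb (-1.99, SE 0.39, adjusted p = 0.00971). Inhbb, lhcgr, hsd17b1 and igf3 are granulosa list members that moved in different directions. The oocyte genes gdf9, bmp15 and ddx4 stood at 0.23, 0.14 and -0.26 with adjusted p = 0.977, 1 and 0.989.

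Small shifts of whole lists passed the list test at this last step without called members. Stroma and smooth muscle genes had a median of 0.57 over 26 genes (adjusted p = 2.81e-05, adjusted p = 0.656 with an estimated correlation; 1 higher adjusted over the list alone) and endothelial genes 0.61 over 20 genes (adjusted p = 0.00258, adjusted p = 0.659 with an estimated correlation; none adjusted over the list alone). Ribosomal protein genes had a median of 0.10 over 91 genes (adjusted p = 9.03e-09, adjusted p = 0.657 with an estimated correlation; 6 higher adjusted over the list alone). Lower medians were found for 47 proteasome genes (-0.10, adjusted p = 0.00149, adjusted p = 0.665 with an estimated correlation), 33 heat shock genes (-0.13, adjusted p = 0.0285, 0.0563 with library totals, adjusted p = 0.657 with an estimated correlation) and 27 inflammation genes (-0.55, adjusted p = 0.000314, adjusted p = 0.657 with an estimated correlation; 2 lower adjusted over the list alone). Surface 300um replicate 2 and Molino 300um replicate 3 had raised markers of other cell types (summed log2 CPM 11.84 and 11.52, against 10.55 to 10.9 in their replicates), as did surface 100_300um replicate 1. The count of 73 rested partly on single libraries, as it was 48 without surface 300um replicate 1, 43 without surface 300um replicate 3, 48 without Pachón 100_300um replicate 2 and 46 without Molino 100_300um replicate 3. With DESeq2 it was 138, and with the 18 compared libraries alone 117.

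Within each population, 300um was compared with 40um, the ends of the size series. Oocyte growth factors were higher at 300um in all 3 populations: gdf9 by 1.83 in surface fish, 2.68 in Pachón and 1.37 in Molino (adjusted p = 9.49e-06, 3.86e-08 and 0.000288), and bmp15 by 2.27, 2.83 and 1.68. The repair gene brca2 rose by 2.73, 3.40 and 3.37 and mcm5 by 2.697, 3.51 and 2.32. Fshr was lower by -2.51, -4.18 and -2.39, cyp19a1a by -3.15, -5.49 and -4.24, and the lipid droplet coat gene plin2 by -3.06, -7.16 and -5.96 (adjusted p = 0.011, 1.12e-05 and 0.000115). Beyond the lists, leading genes at 300um were dact2 in surface fish (3.69) and ADORA1 (3.49) and mapk12b (3.28) in Molino. In Pachón they were the transcription factor hand2 (5.75, SE 0.64, adjusted p = 2.49e-08), EDIL3 (4.75), dmrta2 (4.61) and, with 1 and 3 reads at 40um, pth1r (77-fold, counting interval 13.7 to 3060) and tfap2d (39-fold, 13.2 to 190). Surface fish had 9493 genes that differed (3783 higher, 5710 lower), Pachón 10337 (4421 and 5916) and Molino 8782 (3660 and 5122).

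Genes of blood and immune cells were among the largest falls at 300um. In surface fish hbba2 fell by 8.56 (SE 0.78, adjusted p = 2.81e-09), nt5c2l1 by 8.21, the haemoglobin HBE1 (ENSAMXG00000016437) by 8.43 and nr4a2b by 8.92, and GFI1B was at least 64.4-fold lower. In Molino hbba2 fell by 10.33 (SE 0.81, adjusted p = 1.7e-09; 0.41 against 572 CPM) and nt5c2l1 by 11.24. There tnfrsf18 was 1700-fold lower (counting interval 580 to 8240). In Pachón the largest losses included c1qc (at least 241-fold) and the interleukin il1b (at least 142-fold). Of 24 macrophage and granulocyte genes 21 fell in surface fish, 22 in Pachón and 22 in Molino (adjusted p = 1.13e-05, 0.00031 and 2.46e-08). Adjusted over the list alone 22 fell in surface fish. They had adjusted p = 0.633, 0.659 and 0.633 with an estimated correlation. Of 16 erythrocyte genes 15, 14 and 14 fell, with 1 higher in Pachón and 15 lower in Molino adjusted over the list alone (adjusted p = 2.74e-08, 0.00047 and 1.15e-10). These had adjusted p = 0.284, 0.633 and 0.0606 with an estimated correlation. Of 33 granulosa genes 29, 26 and 23 fell and 1 rose in each population (adjusted p = 0.000152, 2.4e-06 and 0.000298). These had adjusted p = 0.657, 0.633 and 0.657 with an estimated correlation. Inflammation genes were lower for 24, 22 and 23 of 27 members, with 1 higher in each (adjusted p = 1.81e-05, 3.36e-06 and 2.23e-06, each with an adjusted p = 0.633 with an estimated correlation). In surface fish 25 fell adjusted over the list alone.

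Ribosomal protein genes were lower at 300um in 80, 81 and 78 of 91 members, and higher in 3, 2 and 2 (medians -1.48, -1.77 and -1.66, adjusted p = 1.72e-28, 6.22e-31 and 2.91e-36). They had adjusted p = 0.476, 0.439 and 0.31 with an estimated correlation. The lower members were 82, 82 and 78 adjusted over the list alone. Cell cycle genes included 15, 27 and 19 of 42 higher and 8, 3 and 3 lower (medians 0.26, 1.26 and 0.64, adjusted p = 0.0418, 2.74e-08 and 7.07e-05). They had adjusted p = 0.828, 0.633 and 0.665 with an estimated correlation. In Molino 20 rose adjusted over the list alone. DNA repair genes were higher for 12, 21 and 12 of 45 and lower for 7, 5 and 5 (adjusted p = 0.0343, 0.0055 and 0.00897). They had adjusted p = 0.719, 0.659 and 0.659 with an estimated correlation. In surface fish 6 fell adjusted over the list alone. Lymphocyte genes fell for 17 of 20 in surface fish and in Molino with 1 higher in each (adjusted p = 0.00559 and 0.000518). Their values were adjusted p = 0.659 and adjusted p = 0.633 with an estimated correlation. Yolk uptake genes fell for 17 and 18 of 38 members there, against 2 and 1 higher (adjusted p = 0.0343 and 0.0201), and glycolysis genes for 20 and 17 of 34, against 3 and 2 higher (adjusted p = 0.026 and 0.0344, with 22 lower in surface fish adjusted over the list alone). All 4 had an adjusted p = 0.633 with an estimated correlation. Steroidogenesis genes fell in Pachón for 14 of 20 with 1 higher (adjusted p = 0.0131, adjusted p = 0.633 with an estimated correlation). Oxidative phosphorylation genes fell in surface fish for 37 of 92 with 3 higher, or 36 and 3 adjusted over the list alone (adjusted p = 0.0023, adjusted p = 0.815 with an estimated correlation). In Pachón the piRNA list (7 of 14 higher, 1 lower, adjusted p = 0.0416) and the insulin list (23 of 43 lower, 8 higher, adjusted p = 0.0327) passed, with adjusted p = 0.719 and 0.657 with an estimated correlation, and with library totals they missed the threshold at 0.0562 and 0.0768. In Molino the clock list passed (19 of 39 lower, 2 higher, adjusted p = 0.00721, adjusted p = 0.659 with an estimated correlation). Library totals turned the splits of all genes to 5136 higher and 4404 lower in surface fish, 6178 and 4718 in Pachón and 5478 and 4236 in Molino, where DESeq2's size factors gave 2685 and 6001. With the compared libraries alone the surface count was 4321.

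The change from 40um to 300um was compared with that in surface fish as an interaction. Cell content at 40um could give such differences, which was not tested. The change of several insulin signalling genes was lower in Pachón: the receptor substrates irs2a by -3.92 (SE 0.63, adjusted p = 0.000252) and IRS1 by -2.85 (SE 0.46, adjusted p = 0.000271), the translation repressor eif4ebp3 by -3.23 (SE 0.62, adjusted p = 0.00161) and the insulin receptor gene insra by -2.24 (SE 0.50, adjusted p = 0.00594). In surface fish irs2a fell by 1.53 and IRS1 rose by 1.55, while eif4ebp3 and insra stood at 0.22 and 0.15 (adjusted p = 0.688 and 0.73). Of 43 insulin, IGF and mTOR genes 10 were lower and none higher (median -0.38, list test adjusted p = 0.00173, adjusted p = 0.941 with an estimated correlation; 11 lower and 2 higher adjusted over the list alone). Of 42 cell division genes 9 were relatively higher and none lower (median 1.06, adjusted p = 1.37e-09, adjusted p = 0.941 with an estimated correlation; 17 higher adjusted over the list alone), including mcm3 (3.18, SE 0.64, adjusted p = 0.00236), cenpe (2.05, SE 0.40, adjusted p = 0.00196) and the mitotic gene birc5a (2.05). With the 12 compared libraries alone mcm3, cenpe, birc5a, insra and eif4ebp3 missed the threshold. The clock output regulator hlfb was higher by 5.83 and bmal1a and tefb lower by -1.60 and -1.83. In total 1495 genes differed, 629 higher and 866 lower. Among genes with a symbol and a mean log2 CPM of at least 2, the largest differences were EDIL3 (9.60), PCDH1 (6.24), erbb3b (5.99), myb (5.93) and krt5 (5.39) upward and CARF (-5.37), naalad2 (-5.50), tlr18 (-5.65), HBE1 (ENSAMXG00000038014, -6.23) and CASP6 (-6.96) downward. EDIL3, PCDH1, erbb3b and CASP6 had at most 3 reads in 1 of the 4 groups, so their values depend on the prior count of the fit, and naalad2, krt5 and CASP6 missed the threshold without the filter.

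Further lists passed in the Pachón interaction with few called members: oocyte factors (1 of 32 higher, none adjusted over the list alone, median 0.63, adjusted p = 0.00961), germline stem and early germ cells (1 of 13 higher, 3 higher and 1 lower adjusted over the list alone, median 1.16, adjusted p = 0.0292), piRNA (1 of 14 higher, 3 adjusted over the list alone, median 0.74, adjusted p = 0.0399), oxidative phosphorylation (4 of 92 higher, none adjusted over the list alone, median 0.35, adjusted p = 0.00127) and proteasome (1 of 47 higher, also adjusted over the list alone, median 0.46, adjusted p = 0.00127). Granulosa genes (1 of 33 higher, 1 lower, or 1 and 4 adjusted over the list alone, median -1.63, adjusted p = 0.00832) and ribosomal protein genes (median -0.31, adjusted p = 0.00284) had negative medians. The single called gene of the latter list was the kinase RPS6KL1, higher by 2.19, also adjusted over the list alone. These 7 lists had an adjusted p = 0.941 with an estimated correlation. The count of 1495 was 968 without surface 300um replicate 2, 794 without Pachón 300um replicate 1, 926 without Pachón 300um replicate 3, 909 without surface 40um replicate 1, 3519 without surface 40um replicate 2, 3883 without Pachón 40um replicate 1, and 766 and 784 without Pachón 40um replicates 2 and 3. It was 2284 with DESeq2, 2892 with the replicate block and 119 with the 12 compared libraries alone, and library totals split it into 949 higher and 712 lower.

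For Molino the interaction found 138 genes, 73 higher and 65 lower relative to surface fish. Among the largest differences were BANK1 (10.37), bgna, the proteoglycan biglycan (6.32), pcgf5b (5.28), erbb3b (5.12) and ek1 (5.08) upward, and DENND2A (-3.84), NCAM2 (-4.37), EMILIN2 (-4.88) and HBE1 (ENSAMXG00000038014, -7.88) downward. BANK1, bgna, pcgf5b and erbb3b had at most 3 reads in surface 300um libraries, so their values depend on the prior count. Mcm3 was higher by 2.84 (SE 0.63, adjusted p = 0.0211), the only called member of 42 cell cycle genes (also adjusted over the list alone; median 0.34, adjusted p = 0.00482), and bmal1b lower by -1.38 (SE 0.28, adjusted p = 0.0108), the only called member of 39 clock genes (also adjusted over the list alone; median -0.31, adjusted p = 0.0405). No member was called, also adjusted over the list alone, among 92 oxidative phosphorylation genes (median 0.39, adjusted p = 1.75e-05), 47 proteasome genes (median 0.32, adjusted p = 0.00047) or 24 macrophage and granulocyte genes (median -1.90, adjusted p = 0.00832). With an estimated correlation these 5 lists had an adjusted p = 0.941. The count of 138 was 85 without surface 300um replicate 3, 74 and 82 without Molino 300um replicates 1 and 2, 1170 without surface 40um replicate 2, 90 without surface 40um replicate 3 and 84 without Molino 40um replicate 3. It was 392 with DESeq2, 412 with the replicate block and 8 with the 12 compared libraries alone, where mcm3, bmal1b, BANK1 and bgna missed the threshold.

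**Figure D2:**
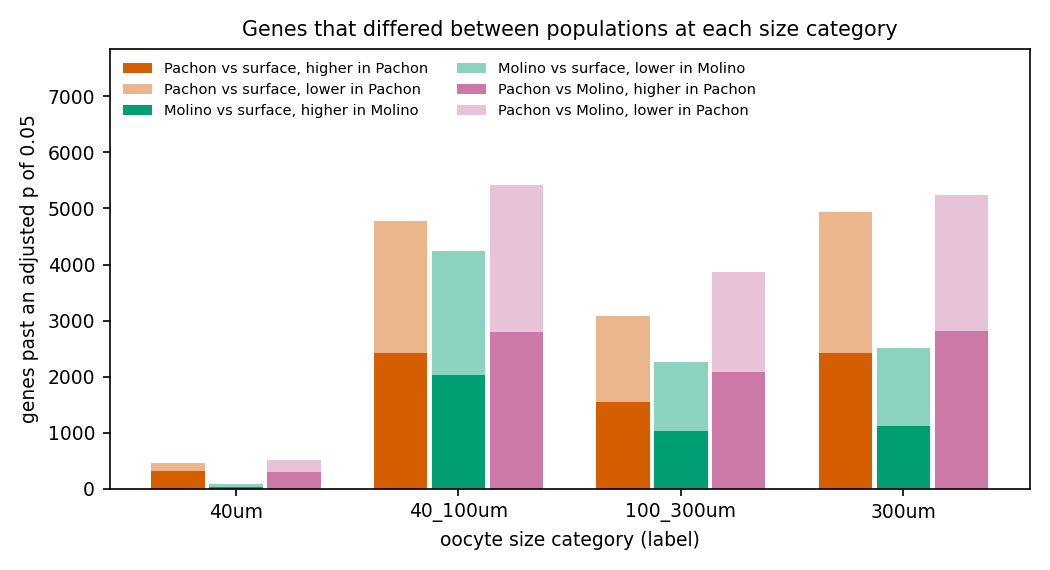
Number of genes past an adjusted p of 0.05 (edgeR quasi-likelihood test) in each population contrast at each size category. Dark and light parts of a bar are genes higher and lower in the population named first.

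Populations were compared within each size category, each of 1 library series. At 300um many genes of translation and respiration were higher in Pachón than in surface oocytes. Reads assigned to genes also differed there, at 65 ± 2.08% in Pachón, 58.6 ± 1.66% in surface and 53.2 ± 2.58% in Molino libraries (SD, n = 3). Of 89 genes in the ribosomal protein list 58 were higher and 1 lower in Pachón (median 0.50, list test adjusted p = 1e-10, but adjusted p = 1 with an estimated correlation, as for every list in the population contrasts), including rpl3 (1.06, adjusted p = 0.00152; 1769 ± 289 against 852 ± 144 CPM, n = 3) and rpl22 (1.09). Of 90 nuclear oxidative phosphorylation genes 47 were higher and 2 lower (median 0.42, adjusted p = 2.26e-06). Oocyte factors such as npm2b (1.07, adjusted p = 0.00495; 278 ± 54.4 against 133 ± 32.8 CPM, n = 3) and the translational regulator zar1l (1.02, adjusted p = 0.00269) were higher for 11 of 30 and lower for 2 (median 0.40, adjusted p = 0.00421), while gdf9 and bmp15 stood at 0.09 and 0.14 (adjusted p = 0.593 and 0.274). Of 42 cell cycle genes 15 were higher and none lower (median 0.27, adjusted p = 0.00714), including pcna (0.95, adjusted p = 0.000185; 835 ± 77.1 against 434 ± 34.1 CPM, n = 3) and the cyclin ccna1 (0.93, adjusted p = 0.00167). Of 40 proteasome genes 11 were higher and 1 lower (median 0.23, adjusted p = 0.0283, but 0.116 with library totals). Adjusted over the list alone, 69 ribosomal protein genes were higher and 3 lower and 52 oxidative phosphorylation genes higher and 3 lower. The other 3 lists kept their counts. Summed markers of other cell types were 545 ± 113 CPM in Pachón and 535 ± 325 in surface fish for granulosa genes, 196 ± 6.62 and 165 ± 32.7 for erythrocyte genes, 595 ± 124 and 1016 ± 470 for stroma genes, and for macrophage genes 80.3 ± 6.59 and 213 ± 274 (SD, n = 3), with 529 in surface replicate 2. Cyp26a1 gave 325 CPM of the Pachón granulosa sum, so equal sums need not mean equal follicle content. Of 15214 tested genes 4931 differed, 2426 higher and 2505 lower.

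Single genes with larger differences at 300um included cbsa (2.38, SE 0.21, adjusted p = 4.64e-05; 155 ± 31.04 against 29.9 ± 7.93 CPM, n = 3), manf (1.64, SE 0.10, adjusted p = 4.51e-06; 106 ± 9.13 against 34.2 ± 2.48 CPM, n = 3), soat2 (2.93, adjusted p = 0.00428), the translational regulator cpeb1a (2.78, adjusted p = 0.000246) and the nuclear receptor nr1d4b (3.08, adjusted p = 0.000973). Ddx4 was higher by 0.59 (adjusted p = 0.00231). Some genes were near 0 in surface oocytes: casq1a (ENSAMXG00000034607) was at least 69.9-fold higher in Pachón, CNGA3 (ENSAMXG00000035630) 434-fold (counting interval 77.6 to 17200) and EDIL3 (ENSAMXG00000043126) 229-fold (63.2 to 1900). Near 0 in Pachón were plpp7a (ENSAMXG00000030606, at least 107-fold lower), GALNT8 (ENSAMXG00000013135, at least 68.4-fold lower) and lrit3a (ENSAMXG00000041737, -7.88, adjusted p = 2.57e-07; 0.21 against 54.0 CPM). CNGA3 and EDIL3 are symbols carried by more than 1 gene, so reads may be shared with a copy, and the bounds and intervals cover counting error only. Library totals split the called genes into 1919 higher and 3287 lower, and without Pachón replicate 1 the count was 3258. With all 36 libraries in 1 fit it was 2563, and npm2b, zar1l, ccna1 and ddx4 missed the threshold.

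The remaining lists at 300um did not pass the list test. Counts are over all genes tested, then adjusted over the list alone where these differ. Germ cell lists held 4 of 11 germline stem and early germ cell genes higher and none lower (adjusted p = 0.2), 4 of 15 meiosis genes higher and 2 lower (0.791), and 3 of 14 piRNA genes higher and 1 lower (0.398). Somatic and blood lists held 4 of 25 granulosa genes higher and 1 lower, then 3 and 1 (0.761; the median was 0.03 and the mean -0.06), 3 of 19 steroidogenesis genes higher and 3 lower (0.962), 1 of 22 stroma genes lower (0.684), 1 of 16 endothelial genes lower, then none (0.895), 1 of 9 erythrocyte genes higher and 1 lower (0.698), 1 of 10 macrophage and granulocyte genes lower (0.534), none of 5 lymphocyte genes (0.956) and 4 of 12 hepatocyte and plasma protein genes lower (0.0951). Metabolic lists held 8 of 27 yolk uptake genes higher and 4 lower, then 10 and 4 (0.957), 4 of 28 cholesterol synthesis genes higher and 8 lower (0.65), 6 of 33 lipid synthesis genes higher and 7 lower, then 7 and 10 (0.897), 9 of 29 fatty acid oxidation genes higher and 3 lower (0.956), 9 of 25 glycolysis genes higher and 6 lower, then 11 and 6 (0.661), and 10 of 34 antioxidant genes higher and 6 lower (0.707). Signalling and stress lists held 10 of 43 DNA repair genes higher and 3 lower (0.518), 2 of 21 apoptosis genes higher and 5 lower, then 3 and 5 (0.962), 9 of 33 heat shock genes higher and 3 lower, then 10 and 4 (0.373), 8 of 40 insulin, IGF and mTOR genes higher and 3 lower (1), 8 of 37 clock genes higher and 5 lower (0.853), 1 of 5 genes with known cavefish alleles higher (0.193), 1 of 18 inflammation genes higher and 1 lower (0.962), and 7 of 34 WNT, BMP and TGF beta genes higher and 6 lower (0.956).

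**Figure D3:**
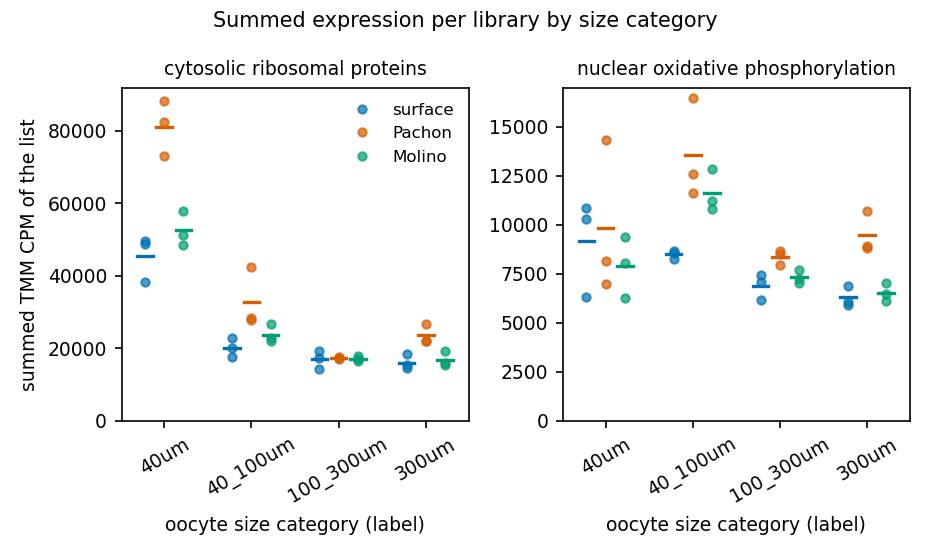
Summed CPM of the ribosomal protein list and the nuclear oxidative phosphorylation list for each library, by size category and population. Bars are means of 3. At 300um the 3 Pachón libraries had 22010 to 26710 CPM of the ribosomal list against 14540 to 18310 in surface and 15460 to 19310 in Molino libraries.

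At 40_100um Pachón oocytes differed from surface oocytes in 4773 of 14377 genes, 2421 higher and 2352 lower. Ribosomal protein genes were higher for 45 of 89 with none lower, or 47 adjusted over the list alone (median 0.51, adjusted p = 6.45e-06). Oxidative phosphorylation genes were higher for 32 of 90 against 4 lower, or 35 and 4 adjusted over the list alone (median 0.40, adjusted p = 0.00174). Granulosa genes were higher for 8 of 23, or 9 adjusted over the list alone (median 1.19, adjusted p = 0.00684), among them igf3 (3.59, adjusted p = 0.00221; 19.3 ± 2.90 against 1.496 ± 0.83 CPM, n = 3), inhbb (3.96, adjusted p = 0.00569) and fshr (2.59, adjusted p = 0.0313). With an estimated correlation all 3 lists had an adjusted p = 1. Summed granulosa markers stood at 544 ± 56.0 CPM in Pachón against 235 ± 49.4 in surface libraries, and macrophage markers at 109 ± 7.84 against 36.3 ± 2.38 (SD, n = 3). Manf was higher by 2.83 (SE 0.16, adjusted p = 1.02e-07; 106 ± 6.18 against 14.1 ± 1.59 CPM, n = 3), nr1d4b by 3.16, plin2 by 2.38 (adjusted p = 0.023) and cbsa by 1.90 (adjusted p = 0.00148), and the clock activator bmal1a was lower by -1.84 (adjusted p = 4.27e-05). Sting1, BNC1 and cacng8a were 633-fold (113 to 25100), 540-fold (96.4 to 21400) and 376-fold (67 to 14900) higher, and plpp7a 238-fold lower. With the summed markers of other cell types as a covariate, 2317 genes differed, and fshr, igf3, nr1d4b and plin2 missed the threshold.

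At 100_300um 3085 of 15494 genes differed between Pachón and surface oocytes, 1557 higher and 1528 lower. Here the ribosomal list (3 of 89 higher, 7 lower, or 3 and 1 adjusted over the list alone, median -0.10, adjusted p = 0.661) and the oxidative phosphorylation list (11 of 90 higher, 4 lower, or 10 and 3, median 0.12, adjusted p = 0.535) did not pass. Manf (2.06), cbsa (1.80), nr1d4b (2.82), hlfb (4.25) and ddx4 (0.48, adjusted p = 0.0265) were higher, as were the photoreceptor genes CNGA3 (623-fold, counting interval 112 to 24700) and rd3 (336-fold, 59.9 to 13300) and BNC1 (7.10). Plasma protein genes, made in liver, were lower: 4 of 12, or 6 adjusted over the list alone (median -3.27, adjusted p = 0.0283, adjusted p = 1 with an estimated correlation), among them plg (-2.48), rbp4 (-3.50) and fgg (-4.30). The summed hepatocyte and plasma protein list reached 1448 CPM in surface replicate 1 against a surface mean of 523 ± 802 CPM (SD, n = 3). Ahsg2 (ENSAMXG00000040479) was 292-fold lower (80.5 to 2420) and plpp7a at least 103-fold lower. Rbp4 and fgg missed the threshold with the covariate and without the expression filter, and ddx4 with all 36 libraries in 1 fit. Leaving out Pachón replicate 1 or replicate 3 gave 1922 and 1973 genes.

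At 40um, where replicates differed most, 458 of 15917 genes distinguished Pachón from surface fish, 321 higher and 137 lower. Some insulin signalling genes were higher in Pachón: irs2a by 3.50 (adjusted p = 0.0151; 1954 ± 726 against 179 ± 86.7 CPM, n = 3), the IGF receptor igf1ra by 3.37 (adjusted p = 0.0186), eif4ebp3 by 3.18 (adjusted p = 0.00822) and igfbp3 by 2.90 (not past the threshold with library totals). Of 41 such genes 4 were higher and none lower, or 9 and 1 adjusted over the list alone (median 0.39, adjusted p = 0.00125, but adjusted p = 1 with an estimated correlation, as for each list below). Granulosa genes were higher for 2 of 30, or 10 adjusted over the list alone (median 1.36, adjusted p = 1.72e-05), namely inhbb (3.86, adjusted p = 0.0112) and fshr (2.96, adjusted p = 0.0323; 97.9 ± 32.5 against 12.9 ± 8.82 CPM, n = 3). The ribosomal list had a median of 0.85 (adjusted p = 1.52e-12) with no called member among 89, also adjusted over the list alone, and summed to 81140 ± 7647 CPM in Pachón against 45520 ± 6244 in surface fish. Erythrocyte genes were lower for 2 of 16, or 4 adjusted over the list alone (median -0.93, adjusted p = 0.00356), cell cycle genes for 1 of 41, also adjusted over the list alone (median -0.65, adjusted p = 0.00125), and hepatocyte and plasma protein genes for 2 of 13, or 1 higher and 4 lower adjusted over the list alone (median -1.14, adjusted p = 0.0194, and 0.0523 with library totals). Macrophage and granulocyte genes (median -1.37, adjusted p = 0.00174) and lymphocyte genes (median -2.12, adjusted p = 0.00351) had no called member among 22 and 16. Adjusted over the list alone, 1 macrophage gene was higher and 1 lower, and no lymphocyte gene passed. Surface replicate 2 had 9325 CPM of macrophage markers, its replicates 1260 and 2704. The chaperone gene dnajb1b was higher by 3.06 (adjusted p = 0.0115), nr1d4b by 4.77 (adjusted p = 0.0107), CNGA3 188-fold (33 to 7470). CELA1 was 235-fold lower, and GALNT8 and lrit3a at least 87-fold and 65.3-fold lower. The count of 458 was 216 and 102 without surface replicates 1 and 3 and 36 and 145 without Pachón replicates 2 and 3. DESeq2 gave 1690, all 36 libraries in 1 fit 4209, the 6 compared libraries alone 217 and the covariate 2450, and library totals split the calls into 212 higher and 191 lower.

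Between Molino and surface oocytes of the 300um category 3 of 37 clock genes were higher and 6 lower, or 6 and 7 adjusted over the list alone. The list did not pass (adjusted p = 0.97). Roraa was higher by 1.57 (adjusted p = 0.0309). The light-responsive repressor per2 (ENSAMXG00000001431) was lower by -2.13 (SE 0.31, adjusted p = 0.00158; 11.8 ± 1.14 against 51.9 ± 24.2 CPM, n = 3), cry5 by -1.70 (adjusted p = 0.000412) and per3 by -1.64 (adjusted p = 0.0452). The pigmentation gene oca2, mutated in several cave populations, was lower by -0.81 (adjusted p = 0.036; 18.3 ± 2.32 against 31.8 ± 8.81 CPM, n = 3), insra was higher by 0.72 (adjusted p = 0.00107) and cbsa lower by -0.74 (adjusted p = 0.0434). Manf was higher by 0.88 (adjusted p = 0.000267) and creld2 lower by -1.12 (adjusted p = 0.00107). Of the elongases of very long fatty acids, elovl4a was higher by 2.18 (adjusted p = 0.0223) and elovl4b lower by -3.18 (adjusted p = 0.00158). Granulosa genes were higher for 7 of 25, also adjusted over the list alone (median 0.66, adjusted p = 0.0436, but 0.0728 with library totals), such as fshr (1.70, adjusted p = 0.00775) and kitlga (1.96), at summed levels of 543 ± 225 CPM in Molino and 535 ± 325 in surface fish (SD, n = 3). Plasma protein genes were lower for 4 of 12, or 1 higher and 8 lower adjusted over the list alone (median -1.97, adjusted p = 0.0194), among them fgg (-2.37) and fgb (-4.10), and yolk uptake genes for 4 of 27, also adjusted over the list alone (median -0.17, adjusted p = 0.0381), among them the clathrin light chain clta (-1.05) and 3 genes named ctsl.1 (-3.22, at least 28.5-fold and at least 38.5-fold lower). These lists had an adjusted p = 1 with an estimated correlation.

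BANK1 (ENSAMXG00000007267) was at least 125-fold higher in Molino at 300um, bgna (ENSAMXG00000014612) at least 69.3-fold and CLIP3 (ENSAMXG00000010359) 247-fold (84.3 to 1200). Not a single read fell in Molino libraries for the guanylate cyclase GUCY2C (ENSAMXG00000008839, at least 323-fold lower), the protease inhibitor timp4.3 (ENSAMXG00000042051, at least 83-fold lower), TMPRSS5 (ENSAMXG00000009829, at least 76-fold lower) and soat2 (ENSAMXG00000042964, at least 6.97-fold lower). Ctsl.1 is a symbol on several genes of a family and GUCY2C a symbol on more than 1, so their reads may be shared. In all 2507 of 15214 genes differed, 1118 higher and 1389 lower. The count was 1592 and 1492 without Molino replicates 1 and 2 and 1443 with all 36 libraries in 1 fit, where oca2, insra, cbsa, manf, per3, roraa, kitlga, fgg and fgb missed the threshold. Cbsa also missed it with library totals, and elovl4a, per3, roraa and TMPRSS5 without the expression filter.

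At 40_100um 4242 of 14377 genes differed between Molino and surface oocytes, 2034 higher and 2208 lower, or 1494 and 2781 with library totals. Per2 was lower by -3.17 (adjusted p = 0.000722; 4.70 ± 3.05 against 42.6 ± 18.1 CPM, n = 3) and bmal1a by -2.06 (adjusted p = 1.96e-05), and the repressor nr1d1 was higher by 2.22 (adjusted p = 0.000463). Of 34 clock genes 5 were higher and 7 lower, and the list did not pass (adjusted p = 0.962). The chaperone hsp90aa1.2 was higher by 4.10 (adjusted p = 0.000236), manf by 1.18 and insra by 0.69 (adjusted p = 0.0152), and creld2 (-1.65), oca2 (-0.94, adjusted p = 0.00453), figla (-1.24, adjusted p = 0.0214) and elovl4b (-3.12) were lower. No list passed. Of the lists higher elsewhere, 20 of 90 oxidative phosphorylation genes were higher and 4 lower (adjusted p = 0.127) and 16 of 89 ribosomal protein genes higher and 4 lower (adjusted p = 0.226). Bgna and ZPLD1 were at least 107-fold and 77.7-fold higher, and GUCY2C, INPP5K and ahsg2 at least 337-fold, 238-fold and 169-fold lower. Oca2, insra and figla missed the threshold with all 36 libraries in 1 fit.

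At 100_300um 2258 of 15494 genes differed between Molino and surface oocytes, 1027 higher and 1231 lower. Per2 (-2.31, adjusted p = 2.4e-05), cry5 (-1.42), per3 (-1.90), creld2 (-1.195), cbsa (-0.99, adjusted p = 0.0122) and elovl4b (-3.38) were lower and nr1d1 (1.47, adjusted p = 0.00294) and manf (1.07) higher, while oca2 stood at -0.95 with adjusted p = 0.0865. Plasma protein genes were lower for 3 of 12, also adjusted over the list alone (median -4.39, adjusted p = 0.0283, adjusted p = 1 with an estimated correlation), such as fgg (-4.53) and plg (-2.03), with surface replicate 1 at 1448 CPM of that list. Rd3 was 235-fold higher (41.8 to 9320). Ahsg2, TMPRSS5 and timp4.3 were at least 182-fold, 115-fold and 79.3-fold lower. Fgg and per3 missed the threshold without the expression filter and with the covariate, as did TMPRSS5, and cbsa and manf with all 36 libraries in 1 fit. Without Molino replicate 1 or 2 the counts were 1290 and 1192.

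At 40um Molino and surface fish differed in 83 of 15917 genes, 35 higher and 48 lower. The follicle transcription factor wt1b was higher by 2.77 (adjusted p = 0.0334; 273 against 37.4 CPM), the melatonin receptor mtnr1ba by 5.04 (adjusted p = 0.0323) and PAMR1 267-fold (47.5 to 10600). The meiotic recombinase dmc1 was lower by -4.21 (adjusted p = 0.0493) and the replication helicase subunit mcm6 by -2.24, ctsl.1 (ENSAMXG00000037672) was at least 43.5-fold lower, and per2 stood at -2.29 (adjusted p = 0.0929). Erythrocyte genes had a median of 0.97 over 16 genes (adjusted p = 4.33e-05; 4 higher adjusted over the list alone), and their summed level was 2563 ± 454 CPM in Molino against 1056 ± 466 in surface fish (SD, n = 3). Granulosa genes (1 of 30 higher, or 2 and 1 lower adjusted over the list alone, median 0.52, adjusted p = 0.0138) and insulin genes (none of 41, or 1 higher adjusted over the list alone, median 0.47, adjusted p = 0.00714) also had positive medians. Meiosis (1 of 15 lower, or 5 adjusted over the list alone, median -1.10, adjusted p = 0.015), hepatocyte (none of 13, or 3 lower adjusted over the list alone, median -0.97, adjusted p = 0.0151), oxidative phosphorylation (none of 90, median -0.39, adjusted p = 0.0151), proteasome (none of 47, median -0.63, adjusted p = 0.00174) and cell cycle genes (1 of 41 lower, or 3 adjusted over the list alone, median -0.47, adjusted p = 0.0128) had negative ones, and with an estimated correlation all had an adjusted p = 1. The count of 83 was 354 and 9 without surface replicates 2 and 3 and 9, 2 and 5 without Molino replicates 1, 2 and 3. It was 201 without the expression filter, 676 with DESeq2, 1974 with all 36 libraries in 1 fit, 40 with the 6 compared libraries, where wt1b, mtnr1ba, dmc1 and mcm6 missed the threshold, and 347 with the covariate, and library totals gave 56 higher and 49 lower.

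At the 3 larger sizes, with all libraries, more genes differed between Pachón and Molino than between either and surface fish. At 40um, with 506 genes against 458 for Pachón and surface fish, the order turned with DESeq2 (1448 and 1690), the replicate block (1117 and 1488), all 36 libraries in 1 fit (3751 and 4209), the covariate (2258 and 2450) and no filter (613 and 615). At 300um 5247 of 15214 genes differed, 2821 higher in Pachón and 2426 lower. Cbsa was higher in Pachón by 3.12 (adjusted p = 7.24e-06; 155 ± 31.04 against 17.9 ± 2.56 CPM, n = 3), per2 by 2.23 (adjusted p = 0.000606; 55.02 ± 3.79 against 11.8 ± 1.14 CPM, n = 3), per3 by 2.44, hlfb by 3.20, the clock output gene nfil3 by 3.00 and oca2 by 1.08 (adjusted p = 0.00481), and insra was lower by -0.47 (adjusted p = 0.00584) and elovl4a by -3.43 (adjusted p = 0.00197). The ribosomal list held 51 of 89 higher and 3 lower, or 59 and 3 adjusted over the list alone (median 0.45, adjusted p = 5.6e-06), such as rpl12 (1.08, adjusted p = 0.000605). Oxidative phosphorylation genes were higher for 41 of 90 and lower for 3, or 54 and 7 adjusted over the list alone (median 0.43, adjusted p = 0.000595), oocyte factors for 15 of 30, also adjusted over the list alone (median 0.39, adjusted p = 0.00351), cell cycle genes for 20 of 42 against 2 lower, or 23 and 2 adjusted over the list alone (median 0.32, adjusted p = 0.0138), and proteasome genes for 17 of 40 against 1 lower, or 19 and 1 adjusted over the list alone (median 0.27, adjusted p = 0.0147, but 0.093 with library totals). With an estimated correlation these 5 lists had an adjusted p = 1. GUCY2C, ctsl.1 (ENSAMXG00000037672), casq1a and soat2 were at least 203-fold, 102-fold, 69.6-fold and 53.3-fold higher in Pachón. Lower were il1rapl1b (-7.61), lrit3a (-8.03, adjusted p = 2.02e-07) and BANK1 (at least 140-fold). Library totals split the calls into 2013 and 3443, and the count was 3413 without Molino replicate 2 and 2972 with all 36 libraries in 1 fit, where oca2 and insra missed the threshold.

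At 40_100um 5412 of 14377 genes differed between the cave populations, 2792 higher in Pachón and 2620 lower. Macrophage and granulocyte genes were higher in Pachón for 4 of 7, or 5 adjusted over the list alone (median 1.86, adjusted p = 0.0269), including coro1a (5.89, adjusted p = 5.62e-06), cd74a (2.73) and irf8 (2.15), at summed levels of 109 ± 7.84 against 17.9 ± 4.66 CPM (SD, n = 3). Ribosomal protein genes were higher for 25 of 89 and lower for 4, or 24 and 4 adjusted over the list alone (median 0.40, adjusted p = 0.0234). Both lists had an adjusted p = 1 with an estimated correlation. Per2 (3.07), per3 (2.42), cbsa (2.11), plin2 (2.09) and fshr (3.63) were higher and gdf9 (-0.48, adjusted p = 0.0176) and elovl4a (-4.75) lower, but plin2 and gdf9 missed the threshold with all 36 libraries in 1 fit. INPP5K, GUCY2C and BNC1 were at least 382-fold, 251-fold and 159-fold higher in Pachón, and il1rapl1b was 717-fold lower (128 to 28400).

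At 100_300um the cave populations differed in 3874 of 15494 genes, 2087 higher in Pachón and 1787 lower, and no list passed. Higher were per2 (2.36), per3 (2.83), cbsa (2.80), nfil3 (2.53), hlfb (3.22), manf (0.99), oca2 (1.04, adjusted p = 0.0435, not past the threshold with library totals) and ddx4 (0.60, adjusted p = 0.00719), and elovl4a was lower by -3.44. Ctsl.1 (ENSAMXG00000037672) and soat2 were at least 101-fold and 60.2-fold higher. CLIP3 was 966-fold lower (173 to 38200) and BANK1 at least 185-fold. Without Molino replicate 1 or 2 the counts were 2508 and 2310.

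At 40um erythrocyte genes were lower in Pachón than in Molino for 8 of 16, or 10 lower and 1 higher adjusted over the list alone (median -2.20, adjusted p = 1e-10, adjusted p = 1 with an estimated correlation). Hbba2 was lower by -4.08 (adjusted p = 0.0166; 32.9 against 572 CPM), rhag by -3.86 (adjusted p = 0.00676) and the erythropoietin receptor epor by -3.27. Summed erythrocyte genes were 906 ± 232 CPM in Pachón and 2563 ± 454 in Molino (SD, n = 3). Macrophage and granulocyte genes (1 of 22 lower, lyz at -4.30, also adjusted over the list alone, median -1.15, adjusted p = 0.000826) and lymphocyte genes (none of 16, also adjusted over the list alone, median -1.53, adjusted p = 0.00351) had negative medians. The ribosomal list (1 of 89 higher, RPL22 at 4.11, also adjusted over the list alone, median 0.73, adjusted p = 2.18e-07) and the oxidative phosphorylation list (none of 90, also adjusted over the list alone, median 0.43, adjusted p = 0.0436, and 0.143 with library totals) had positive ones. With an estimated correlation all 4 had an adjusted p = 1. Nr1d4b was higher by 2.93 (not past the threshold with library totals), hsp90aa1.2 by 3.15 and ctsl.1 (ENSAMXG00000037672) at least 48.7-fold. Elovl4a was lower by -4.50 and lrit3a at least 105-fold. Of 15917 genes 506 differed, 298 higher and 208 lower, or 220 and 340 with library totals. The count was 258, 131 and 297 without Pachón replicates 1, 2 and 3 and 70 and 14 without Molino replicates 1 and 2.

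The last question was which genes differed from surface fish the same way in both cave populations. At all 4 sizes 8 genes did, 2 higher and 6 lower in both. Those with a symbol were lower: KNTC1, a mitotic checkpoint gene, with a mean of -2.90 over the 8 contrasts, IRAG1 (-4.26) and the muscle calcium pump atp2a1 (-4.74). The 2 higher genes, ENSAMXG00000031343 (7.70) and ENSAMXG00000003353 (4.49), have no symbol in the table. The count was 26 and 0 without surface 40um replicates 2 and 3, 5, 1 and 4 without Pachón 40um replicates 1, 2 and 3 and 0 without each Molino 40um replicate. Without the 40um category it was 375, 191 higher and 184 lower. Those 375 included rd3 (6.64) and erbb3b (5.18) higher and ahsg2 (-8.49) and timp4.3 (-7.14) lower, genes chosen after their values were seen.

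Within sizes, 24 genes at 40um (14 higher, 10 lower), 1574 at 40_100um (792 and 782), 743 at 100_300um (387 and 356) and 1020 at 300um (508 and 512) were called the same way in both cave populations, and 0, 311, 130 and 187 in opposite ways. At 40_100um library totals gave 575 higher and 1028 lower. Independent lists would share 0.706 higher and 0.413 lower genes at 40um, 343 and 361 at 40_100um, 103 and 121 at 100_300um and 178 and 229 at 300um, and unchanged groups simulated against the surface libraries shared a median of 0 and at most 1. The fold changes of the 2 contrasts correlated across genes at 0.368, 0.296, 0.268 and 0.298, below the 0.492, 0.492, 0.497 and 0.503 of the simulations, which share controls and hold no effects. Their covariance exceeded the simulated one by 0.287, 0.474, 0.322 and 0.376 (for 300um 0.45 against 0.0738 ± 0.0038, SD of 20 simulations). Both contrasts use the same 3 surface libraries, which cannot be split. The simulations take off their noise only as far as the fitted dispersion describes it. The counts were 82 and 1 at 40um without surface replicates 2 and 3, 5 and 15 without Pachón replicates 2 and 3, and 3, 1 and 2 without Molino replicates 1, 2 and 3. They were 476 and 448 at 100_300um without Molino replicates 1 and 2, and 666 at 300um without Molino replicate 2.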

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

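The correlation, library series, scaling and split tests given here were chosen only after the results they examine had been seen; the bounds of the depth, covariate, smaller-oocyte and near-zero-read tests were written before those tests were run, with the covariate itself chosen after the main results.

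The change from 40um to 300um differed between Pachón and surface fish in 1495 genes, among the largest EDIL3 (9.60), PCDH1 (6.24), erbb3b (5.99), myb (5.93), krt5 (5.39), CARF (-5.37), naalad2 (-5.50), tlr18 (-5.65), HBE1 (-6.23) and CASP6 (-6.96). Between Molino and surface fish it differed in 138 genes, among the largest BANK1 (10.37), bgna (6.32), pcgf5b (5.28), erbb3b (5.12), ek1 (5.08), DENND2A (-3.84), NCAM2 (-4.37), EMILIN2 (-4.88) and HBE1 (-7.88). Of 60 splits of the same libraries, 9 reached the Pachón count, with up to 4801 genes, and 13 reached the Molino count, with up to 2850. A split can keep population differences within a size and ignores possible pairing by replicate number. The splits thus neither show nor exclude chance for either. Reads that fall in no annotated gene, which no comparison used, made up 29.2% of the reads at 40um, 15.4% at 40_100um, 18.2% at 100_300um and 19.2% at 300um. Their content was not analysed.

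Markers of follicle, stroma and blood cells were far higher at 40um than at 40_100um. Over the 9 libraries at 40um, summed markers of other cells and oocyte factors correlated at r = -0.929 (Spearman rho -0.967, exact permutation p = 0.000419 for r, r = -0.894 without the 2 farthest libraries, 1 relation examined). RNA from other cells would give this, but shares of the same reads can oppose anyway, and the permutation ignored population. Lower depth is excluded as the whole cause: 81.5% of the 7989 genes lower at 40_100um stayed called with libraries thinned to equal depth. Library series, confounded with size at 40um, stays open: 73 genes differed between 300um and 100_300um, which also differ in series. A biological difference of early oocytes cannot be separated from either in whole-sample RNA.

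Ribosomal protein and oxidative phosphorylation genes were higher in Pachón than in surface fish at 300um. With other cells' summed markers as a covariate the ribosomal median was 0.507, against 0.503 without it. The share they measure is excluded as the whole cause. Scaling is excluded as the whole cause for the 3 other scalings tried, since the lowest ribosomal median under them was 0.381. Smaller oocytes in the Pachón libraries stay possible: across 15035 genes outside these lists, the Pachón difference correlated at r = -0.135 with the step from 40_100um to 100_300um in Molino, a weak relation over genes that are not independent. The 2255 genes that rose at that step had a median difference of -0.335 and the 409 that fell 0.172, the directions smaller oocytes predict. The ribosomal list itself had a median of -0.326 at that step, smaller in size than the 0.503 to be explained. The Molino difference and the Pachón step correlated at r = 0.02. At 100_300um, where these lists did not pass, the Pachón difference and the Molino step correlated at r = -0.1. Reads assigned to genes were also higher in Pachón, and library quality was not tested. A difference between the populations themselves was not separated from such staging.

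Genes with almost no reads in 1 population and many in another at 300um numbered 270. Of these, 37.4% differed the same way by at least 8 times at all 3 other sizes, and 73.2% of the 138 tested at every size did (101 genes, 95% interval 65 to 80.4). The bound first written for this test was wrong, because the 132 pairs removed by the expression filter at some size have no fold there. This was noted after the first value was seen. The 138 are themselves selected by expression at the other sizes, so neither share decides. An inherited difference in expression or a variant against the reference could both give this and stay open. Reads shared with a paralog stay open too: 31 of the genes share a symbol, and 19 of these still differed at least 4 times when copies were summed, while 10 fell under 2 times.

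The real grouping was set against other splits. For the 12 population contrasts and the 3 contrasts of 300um with 40um within a population, 10 splits are too few: 1 of 10, the real one, reached the count, and the highest other called 0 genes for Pachón against surface and against Molino at each size, 0, 1, 1 and 1 for Molino against surface in rising size, and 1580, 0 and 0 for 300um against 40um in surface, Pachón and Molino. For the 3 size steps 1 of 60 splits reached the count, with others at up to 10202, 4437 and 0 genes in rising size. For genes shared by both cave populations 3, 1, 4 and 1 of 100 splits reached the count in rising size, with others at up to 57, 1257, 1013 and 113, and for all 4 sizes 1 of 100, with others at 0.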

How the results depend on the processing

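The covariate, the 2 libraries left out and the 3 sizes without 40um were chosen after seeing the results. The other alternatives were planned.

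DESeq2's size factors, library totals and leaving out the 50 most abundant genes moved no count of called genes by more than 1.5 times, nor did leaving out the 2 libraries with raised markers in the 5 results where it was run. The cause was not tested for the following moves. With DESeq2's Wald test the counts at 40um were 1690 for Pachón against surface, 676 for Molino against surface and 1448 for Pachón against Molino; they were 138 for 300um against 100_300um, 2284 and 392 for the Pachón and Molino interactions, 203 for genes shared at 40um and 49 at all 4 sizes. Without the filter they were 201 for Molino against surface at 40um, 56 shared at 40um and 18 at all 4 sizes. With all 36 libraries in 1 fit, which takes its dispersion from every size, they were 4209, 1974 and 3751 for the 3 population contrasts at 40um and 2563, 1443 and 2972 at 300um, and 750, 932 and 472 for genes shared at 40um, 40_100um and 300um and 81 at all 4 sizes. With only the 6 libraries compared they were 217 and 40 for Pachón and Molino against surface at 40um. With only the groups compared they were 117 for 300um against 100_300um, 4321 for 300um against 40um in surface and 119 and 8 for the interactions. There samples are fewer and the common dispersion of 0.129 (0.246 at 40um) is not used. With the covariate they were 2450, 347 and 2258 for the 3 population contrasts at 40um, 2317 for Pachón against surface at 40_100um, and 131, 880 and 1213 for genes shared at 40um, 40_100um and 100_300um. Without 40um 375 genes were shared at all sizes.

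With the replicate block the counts were 1488, 193 and 1117 for the 3 population contrasts at 40um, 195 for 300um against 100_300um, 2892 and 412 for the interactions, 73 shared at 40um and 13 at all 4 sizes; no other count moved that far. Over 54 pairs of libraries of the same population and number but different size, deviations correlated at a median of 0.34, a minimum of 0.037 and above 0.1 in 49, and 36 of 36 libraries were closest to their own number, a hint that numbers may pair samples across sizes. Over 36 pairs of the same size and number but different population the median was 0.046, above 0.1 in 10, so the block across populations has little support.

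Leaving out each library in turn gave these ranges. Pachón against surface: 36 to 540 at 40um, 3614 to 4318 at 40_100um, 1922 to 3975 at 100_300um and 3258 to 5873 at 300um. Molino against surface: 2 to 354, 3003 to 3729, 1192 to 2618 and 1492 to 2873. Pachón against Molino: 14 to 339, 4382 to 4982, 2310 to 3722 and 3413 to 4408. Size steps: 13247 to 14264, 5040 to 6241 and 43 to 99. 300um against 40um: 8040 to 9796 in surface, 9115 to 11186 in Pachón and 6657 to 9289 in Molino. Interactions: 766 to 3883 for Pachón and 74 to 1170 for Molino. Shared genes: 1 to 82, 1167 to 1373, 448 to 1041 and 666 to 1365 in rising size, and 0 to 26 at all 4.

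Of 594 list and contrast pairs, 119 passed with the preset and 0 with an estimated correlation, 121 with library totals and 148 with fry. Fry kept 68 of the 119 and none of the 14 for interactions. No named gene reversed under any alternative. Calls of named genes were lost for 29 with all 36 libraries in 1 fit, 23 with only the groups compared, 17 without the filter, 14 with only the 6 libraries, 11 with the covariate, 6 with library totals and 3 with DESeq2's size factors.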
